A study of Xenopus laevis with 18 samples.

How the data were processed

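The 18 libraries were made from poly-A RNA of explants excised at stage 9, with 500 to 1000 ng of RNA, a library kit that does not mark strand and paired reads of 150 bp, per the labels' protocols. Embryos were injected at stage 4. Groups were taken from the sample titles: uninjected, spdef morpholino or foxq1 morpholino, at an early time or at stage 25, with 3 replicates each. No control morpholino was in the design. By the labels the replicate number is the number of the experiment. Early replicate 3 is stage 18 in the labels and stage 16 in the file headers; the labels were followed.

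The deposited count per gene model was made by the authors with featureCounts on mapped reads, per the submitters' processing notes and the file headers. The aligner, the genome build and the featureCounts settings are not given in the sources used here. The 4 deposited tables of the authors' own comparisons were made with DESeq2 1.22.1, per the submitters' processing notes, with a design that is not given in the sources used here. They hold the mean normalized signal over libraries, the log2 fold change with its standard error, the Wald score and the p-value, per the file headers of the deposited tables that have one; one table has no header line and its columns were read in the order of the others. The deposited stage 25 table for the foxq1 morpholino holds 1357 genes, with a largest adjusted p of 0.0495, while the other deposited tables hold 51017.

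Gene names came from the authors' deposited tables and, for 3515 of 14818 names beginning with LOC, from a RefSeq gene table of assembly Xenopus_laevis_v10.1, in which 11795 of these IDs were found. No coordinates were used. Of 51017 gene models 2668 had no name, 14341 were .L and 10761 were .S. Reads of near-identical homeologs or paralogs can be split by the counting in a way not known here, and reads of a gene and an overlapping antisense gene cannot be told apart, so single homeologs and members of families such as hes5, krt5 and lonrf are uncertain to that extent. Total counts per library, divided by 1e6, ran from 28.6 to 74.58. No pair of libraries of one group agreed within sampling noise (smallest chi-square per degree of freedom 82.24). Nothing but the experiment number says whether replicates came from separate animals, so p-values speak for these experiments only.

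Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a minimum count of 10 and total of 15, TMM factors, robust quasi-likelihood fit and test, Benjamini-Hochberg adjustment, threshold 0.05). Early comparisons were fitted on the 9 early libraries with a stage 16 or 18 term (5 residual degrees of freedom), stage 25 comparisons on the 9 stage 25 libraries (6), the stage comparison on the 6 uninjected libraries (4), and the interactions on all 18 (11). The common biological coefficient of variation was 0.3775, 0.5645, 0.498 and 0.5089, and 0.3246, 0.3526, 0.4489 and 0.4526 with the replicate block. The replicate numbers pair the libraries, since the labels give the experiment and the deviations of same-numbered libraries from their group means correlated in 18 of 18 pairs (0.334 to 0.816). The blocked fit is an alternative, and its values stand beside the counts of genes, the counts of list members and the list tests where they change a call or move a count by over 1.5 times. CPM values use TMM-scaled library sizes. Counts in the log2 scale of the component analysis had a prior count of 2.

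Genes named in the text followed a rule fixed before the data were examined. It took the spdef and foxq1 homeologs, and the 8 rising and 8 falling genes with the largest log2 fold change among those past the threshold with a mean of at least 5 CPM, a symbol and one direction in all 3 same-numbered pairs (5 per direction between morpholinos). It also took up to 3 passing members of each list by adjusted p, or up to 2 where none passed. Other genes were named after their values were seen, namely smad4.1.S, slc26a4.L and those of the closing observations. The 19 gene lists, also fixed beforehand, were multiciliated cell regulators, cilia structure, ionocyte, small secretory cell, goblet and mucus, endoplasmic reticulum and secretory machinery, basal cell, superficial epithelium, Notch pathway, hes and hey family, cell cycle, p53 and morpholino response, heat shock and stress, neural, neural crest, mesoderm and muscle, endoderm, blood and immune, and cement gland and hatching gland. They were tested in 5 comparisons with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry, adjusted over 95 tests. By fry, 1 list passed, the p53 and morpholino response with the spdef morpholino at the early time (adjusted p = 0.0387), and 0 passed with the replicate block (adjusted p = 0.0677 for this list).

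Alternatives fixed beforehand were the replicate block, RLE factors, no filter, DESeq2 1.42.0, an absolute log2 fold change of at least 1, homeologs summed, each replicate number or library left out, no stage term and only the groups compared. Added after the data were seen were the developmental index as a covariate and the block on replicates 1 and 2. The index is the position of a library between the early and stage 25 controls of the other experiments, over genes that differ between them by at least 2 on the log2 scale. Overlaps were set beside 20 simulations of unchanged groups against the same controls. These drew each gene separately, so changes that genes share within a library are left out of them.

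The scripts were tested on simulated counts in which 200 genes were changed. Without the block, 0% of genes changed 1.5-fold and 0% to 6% of those changed 2-fold were recovered in each comparison. Changes of that size are thus mostly missed where as few as 200 genes change. The adjustment of p-values is less strict where more genes change, so these rates do not describe fits that called many more. In the early spdef comparison 2731 of 3442 called genes changed at least 2-fold and the others less. Of genes changed 4-fold and 8-fold, 58% and 78% were recovered for the spdef morpholino at the early time (25520 genes), 54% and 86% for foxq1 (25596 genes), and 52% and 92% between morpholinos (25581 genes). At stage 25 the values were 10% and 50% for spdef (25478 genes), 12% and 52% for foxq1 (25352 genes) and 12% and 58% between morpholinos (25858 genes). They were 4% and 16% for the control stage comparison (24185 genes), and 14.3% and 46.9% (28082 genes) and 20% and 68% (28094 genes) for the spdef and foxq1 interactions. Unchanged genes were called as well. They numbered 6 (spdef), 6 (foxq1) and 7 (between morpholinos) early, and 2, 1 and 1 at stage 25. For the control stage comparison there was 1, and for the interactions 0 and 4. The 6 of the early spdef comparison stood beside 3, 29 and 39 genes recovered at 2-fold, 4-fold and 8-fold.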

Results

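Messenger RNA was sequenced from mucociliary organoids of the frog Xenopus laevis. An organoid of this kind is an explant of the animal cap, the prospective epidermis of the blastula, which in culture forms a ciliated and mucus-secreting epithelium. Explants came from uninjected embryos or from embryos injected with 3 pmol of a morpholino, an antisense oligonucleotide that blocks translation or splicing of its target, against spdef or against foxq1. Both targets encode transcription factors known from mucus-secreting cells. The series title places the work in the study of Notch signalling and Hes factors in mucociliary cell fate. The comparisons address which transcripts differ when either factor is targeted. Each of the 3 treatments was collected at an early time and at stage 25 with 3 replicates, giving 6 groups and 18 libraries. By the labels, early replicates 1 and 2 were collected at stage 16 and early replicate 3 at stage 18. In each library 30927 to 34443 gene models had at least 1 count. X. laevis is allotetraploid, so most genes have a homeolog on the L and the S subgenome, written .L and .S.

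The libraries separated first by time, except for the stage 25 morpholino libraries of replicate 3. The first principal component of log2 CPM (counts per 1e6 of the TMM-scaled library size) held 51.9% of the variance and the second held 12.5%. Replicate 3 of both morpholinos stood apart at stage 25, at 59.6 (spdef) and 5.2 (foxq1) on the first component. Both values lie within the range of the early libraries, -5.1 to 231.2. The stage 25 libraries of replicates 1 and 2 lay between -201.8 and -137.1, and the uninjected replicate 3 lay inside that range, at -142.7. At the early time, replicate 3 lay at 161.1, 231.2 and 222.8, against -5.1 to 139.6 for the other early libraries. Transcripts of the multiciliated cell regulator mcidas (mcidas.S) showed the same separation at stage 25. They had 509 CPM and 211 CPM in the replicate 3 libraries of the spdef and foxq1 morpholinos and at most 7.33 CPM in the other stage 25 libraries. One gene model, smad4.1.S, took 3.93% of the counts of the early uninjected replicate 2 and 5.6% of those of the stage 25 foxq1 morpholino replicate 3, against at most 1.29% in any other library.

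The targeted genes were examined first. With the spdef morpholino, spdef.S, the single homeolog measured, had 12.7 ± 2.5 CPM (SD, n = 3) at the early time against 26 ± 18.4 CPM in uninjected explants. Its log2 fold change of -0.85 ± 0.45 (SE) did not pass the test (adjusted p = 0.239). It was lower in 2 of 3 same-numbered pairs, with 15.5 CPM against 9.55 CPM in pair 1, and the value was -0.4 without uninjected replicate 3. With the foxq1 morpholino, foxq1.L fell by 1.49 ± 0.37 on the log2 scale (adjusted p = 0.0487), from 16.5 ± 12.6 to 5.85 ± 2.74 CPM. The other homeolog, foxq1.S, had a log2 fold change of -1.19 (adjusted p = 0.119). Both foxq1 homeologs fell with the spdef morpholino, foxq1.L by 2.52 ± 0.39 (adjusted p = 0.0109) and foxq1.S by 2.41 ± 0.45 (adjusted p = 0.0163). Each was lower in 3 of 3 same-numbered pairs. The level of foxq1.S was low, at mean values of 1.26 CPM uninjected and 0.221 CPM with the spdef morpholino. The value of spdef.S with the foxq1 morpholino was -1.09 (adjusted p = 0.161), and -0.56 without uninjected replicate 3. At stage 25 no targeted gene passed the edgeR test in either morpholino comparison. In the authors' deposited DESeq2 comparison foxq1.L was higher with the spdef morpholino at that stage (0.95 ± 0.31, adjusted p = 0.0268). The largest edgeR values at stage 25 were those of foxq1.L, at 0.90 and 1.08 with the spdef and foxq1 morpholinos. These were 0.26 and -0.09 without replicate 3 of the morpholino, 1.65 and 1.83 without uninjected replicate 3, and 1.04 and 0.68 without both. Of the 12 tests of targeted genes in the 4 morpholino comparisons 3 passed. The number was 4 by DESeq2. In edgeR it was 0 without the stage 16 or 18 term, 0 on leaving out replicate 1 or replicate 3, and 1 on leaving out replicate 2. Since a morpholino can act without lowering its target's transcript, these levels neither show nor exclude a knockdown. The transcript level also does not check the labels of the spdef libraries.

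**Figure D1:**
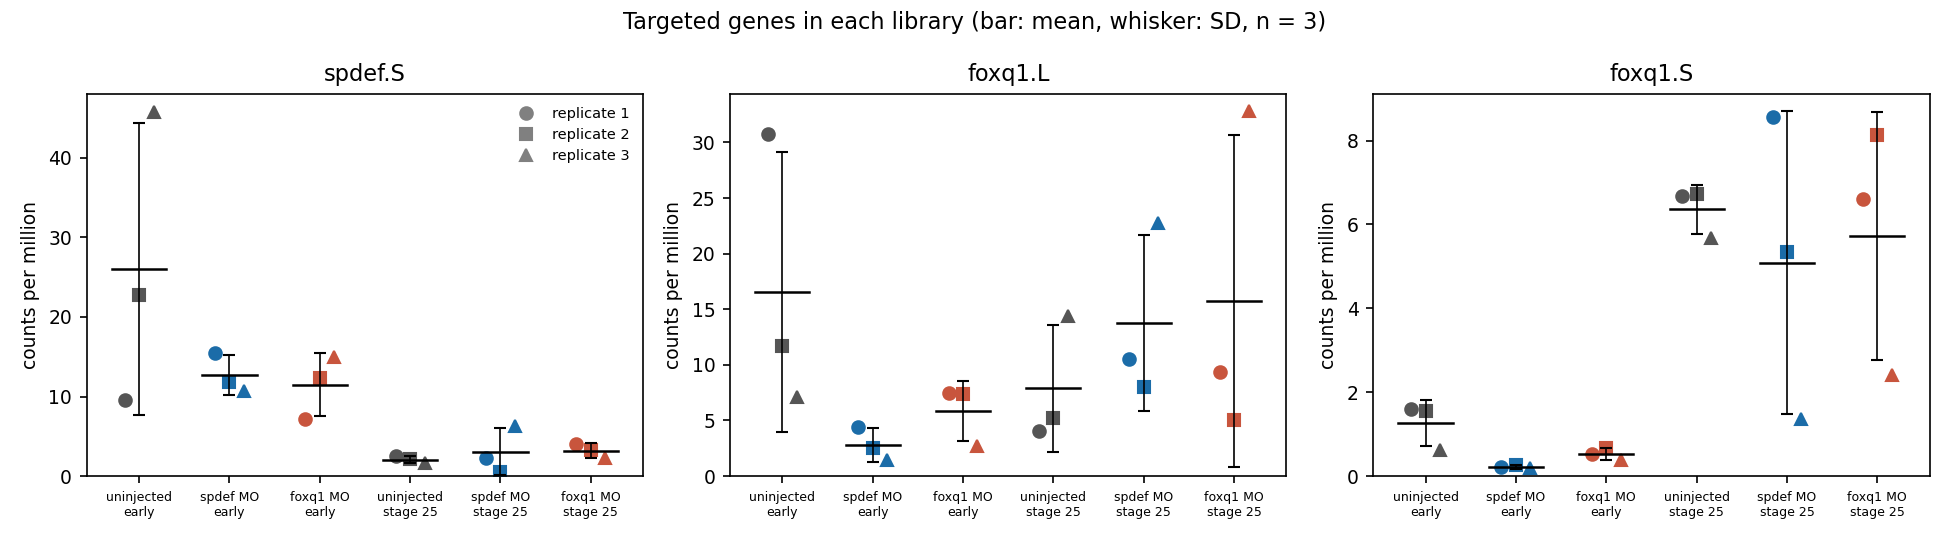
CPM (vertical axes, linear, from 0) of spdef.S, foxq1.L and foxq1.S in each of the 18 libraries, grouped by treatment and time; symbols mark the replicate number, bars the group mean and whiskers the SD over 3 libraries. Early foxq1.L lay between 1.42 and 4.42 CPM with the spdef morpholino and between 7.13 and 30.8 CPM in uninjected explants.

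With the spdef morpholino at the early time, 75 of 86 genes of cilia structure and 11 of 36 multiciliated cell regulators fell, and 21 of 60 genes of the p53 and morpholino response list rose. As sets by camera these lists gave adjusted p = 3.13e-40, 0.000361 and 7.23e-13, and adjusted p = 0.681, 0.718 and 0.681 with an estimated correlation. In all, 3442 of 26868 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, of which 1514 rose and 1928 fell. Of 86 measured genes of cilia structure, 75 fell and 0 rose (80 and 0 adjusted over the list alone). The dynein intermediate chain gene wdr78.S fell by 1.91 ± 0.20 on the log2 scale (adjusted p = 0.00346), from 76 ± 17.6 to 20.4 ± 3.84 CPM. The intraflagellar transport gene ift88.S fell by 1.81 ± 0.19 and the axonemal central apparatus gene spag6.S by 2.30 ± 0.24, both with adjusted p = 0.00348. The median level of the cilia genes in replicate 3, which stood apart at this time too, was 5.22 log2 CPM in uninjected explants and 2.35 with the morpholino, against 6.5 and 4.85 in replicate 1 and 5.8 and 4.64 in replicate 2. Among 36 multiciliated cell regulators 11 fell and 2 rose (16 and 2 adjusted over the list alone). The fallers included mcidas.S (-1.42 ± 0.30, adjusted p = 0.0221), which drives multiciliated cell fate, and the kinase gene nek10.L (-2.37 ± 0.49, adjusted p = 0.0203). In the other direction gmnc.L, which acts upstream of mcidas, rose by 3.25 ± 0.70 (adjusted p = 0.0221), with 108 CPM in replicate 3 against 6.1 and 4.61 CPM in replicates 1 and 2 of the morpholino.

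Members of 3 secretory lists were examined next in the same comparison. By camera the goblet and mucus, small secretory cell and endoplasmic reticulum lists gave adjusted p = 0.000569, 0.00398 and 0.0035, and adjusted p = 0.681, 0.681 and 0.736 with an estimated correlation. Of 31 goblet and mucus genes 7 fell and 1 rose (11 and 2 adjusted over the list alone), among them both foxq1 homeologs. The secreted lectin gene itln1.L fell by 3.88 ± 0.60 (adjusted p = 0.0109) from 3170 ± 2370 to 382 ± 320 CPM. Small secretory cells are the serotonin-releasing cells of this epidermis. Of 16 genes of their list 4 fell (8 adjusted over the list alone). They included the vesicular monoamine transporter slc18a1.S (-2.05 ± 0.50, adjusted p = 0.0308), the vesicle GTPase rab3a.S (-1.64 ± 0.33, adjusted p = 0.0188) and the transcription factor foxa1.L (-2.69 ± 0.69, adjusted p = 0.0368). Over all genes tested 1928 of 26868 fell, a larger share than in the ionocyte list, which is named for acid and base transporting cells. Of 55 genes of this list 3 fell and 0 rose (3 and 0 adjusted over the list alone, 3 and 2 over all genes with the block). These were the anion exchanger slc4a1.S (-2.02 ± 0.40), the proton pump subunit atp6v0a1.L (-2.10 ± 0.45) and the cation-chloride cotransporter slc12a2.L (-0.96 ± 0.22). The endoplasmic reticulum and secretory machinery list had 14 fallers and 1 riser among 98 genes (19 and 2 adjusted over the list alone). The COPII and COPI coat genes sec24d.S (-0.94 ± 0.19) and copb1.L (-1.06 ± 0.22) fell, and xbp1.L, a regulator of the unfolded protein response, rose (0.80 ± 0.17). Superficial epithelium genes fell in 19 of 78 cases and rose in 1 (22 and 1 adjusted over the list alone), including krt19 (-1.57 ± 0.30) and the uroplakin gene upk3b.L (-0.96 ± 0.19). Basal cell genes went both ways, 4 up and 5 down of 36 (6 and 10 adjusted over the list alone). The hemidesmosomal collagen gene col17a1.L rose by 4.17 ± 0.71 (adjusted p = 0.0127), against the keratin genes krt5.7.S and krt5.7.L at -1.26 ± 0.25 and -1.31 ± 0.27.

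In the p53 and morpholino response list 21 of 60 genes rose and 0 fell with the spdef morpholino (23 and 0 adjusted over the list alone). The p53 ubiquitin ligase gene mdm2.L rose by 2.93 ± 0.18 (adjusted p = 0.000718), mdm2.S by 1.57 ± 0.16 (adjusted p = 0.00348) and the death receptor gene eda2r.L by 3.54 ± 0.35 (adjusted p = 0.00346). Of 108 cell cycle genes 19 rose and 3 fell (31 and 12 adjusted over the list alone), and the set did not pass by camera (adjusted p = 0.0501). The mitotic cyclin ccnb1.S was at 3.09 ± 0.51 and the ribonucleotide reductase subunit rrm2.2.L at 2.56 ± 0.49, against -2.64 ± 0.42 for the replication licensing gene mcm5.S. The Notch ligands dll1.L (2.05 ± 0.27, adjusted p = 0.0064), jag1.L (1.47 ± 0.32) and jag2.L (1.86 ± 0.44) were among the 4 of 75 Notch pathway genes that rose (3 adjusted over the list alone, 8 over all genes with the replicate block). Over all genes tested 1514 of 26868 rose, a share close to that of this list. The gene jag2.L was low, at mean values of 0.416 CPM uninjected and 1.67 CPM with the morpholino. It was among the named genes that did not pass in the authors' deposited DESeq2 comparison (adjusted p = 0.172). In the hes and hey family 1 of 24 genes rose (1 adjusted over the list alone, 3 over all genes with the block), which was hes6.1.S at 1.23 ± 0.29 (adjusted p = 0.0277). The largest rises of single genes were those of the RING finger genes lonrf3.S (7.71 ± 0.68, from 1.46 ± 0.804 to 450 ± 545 CPM) and lonrf3.L (6.50 ± 0.69), the heme-binding protein gene hebp2.L (6.56 ± 0.55), pik3r6.S, p2ry2.S, nif.L, cyp27c1.S and ppp1r14c.L, the last being at 4.34 ± 0.45. The largest falls were those of cbm20.L (-4.71 ± 1.18), slc6a3.S (-4.62 ± 1.27), the axonemal dynein gene dnah2.L (-4.47 ± 0.88), fbxw10.L, dzip1l.S, kiaa1549l.S, spata18-like.S and itln1.L. Genes of further tissues moved in small numbers. Fallers were 4 of 26 neural crest genes (4 adjusted over the list alone, 8 over all genes with the block), 4 of 36 mesoderm and muscle genes (4 adjusted over the list alone) and 2 of 21 members of the endoderm list (4 down and 2 up adjusted over the list alone, 3 down and 1 up over all genes with the block). They were also 3 of 15 cement gland and hatching gland genes (4 adjusted over the list alone, 5 down and 1 up over all genes with the block) and 2 of 41 neural genes, with 1 rising (0 adjusted over the list alone). The 2 fallers of the endoderm list were hhex.L (-2.35 ± 0.58) and endod1.S (-0.69 ± 0.19). The latter had 99.6 CPM in uninjected explants, so its fall need not speak of endoderm. In contrast, 3 of 47 heat shock and stress genes (1 adjusted over the list alone, 5 up and 2 down over all genes with the block) and 1 of 19 blood and immune genes rose (0 adjusted over the list alone, 1 up and 1 down with the block).

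Tested as sets against all other genes (camera with a preset correlation of 0.01, Benjamini-Hochberg over 95 tests), the spdef morpholino lists lower at the early time were cilia structure (adjusted p = 3.13e-40), superficial epithelium (0.000152), multiciliated cell regulators (0.000361) and goblet and mucus (0.000569). None of these held when the correlation between genes was estimated from these libraries, with adjusted p = 0.681, 0.718, 0.718 and 0.681. Also lower were endoplasmic reticulum (0.0035; 0.736 with an estimated correlation), small secretory cell (0.00398; 0.681), mesoderm and muscle (0.0268; 0.718) and ionocyte (0.0396; 0.78, and 0.0656 with the replicate block and the preset correlation). Higher lists were p53 and morpholino response (adjusted p = 7.23e-13; 0.681 with an estimated correlation) and hes and hey (0.00441; 0.718). Of the 39 list calls of the 5 main comparisons 0 held with an estimated correlation. The ionocyte call also ended without replicate 1 or 3 (adjusted p = 0.238 and 0.205), and the mesoderm and muscle call without replicate 2 or 3 (0.235 and 0.055). The gene count depended on how replicates were treated. It was 0 in edgeR without the stage 16 or 18 term, 6171 by DESeq2, and 54, 934 and 78 without replicate 1, 2 or 3. Leaving out single libraries gave 670 and 1284 (uninjected replicates 1 and 3) and 1548, 419 and 639 (spdef morpholino replicates 1, 2 and 3).

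With the foxq1 morpholino at the early time, 64 of 86 genes of cilia structure and 13 of 36 multiciliated cell regulators fell. As sets by camera these lists gave adjusted p = 1.17e-46 and 1.15e-07, and adjusted p = 0.681 and 0.718 with an estimated correlation. In all, 1749 genes of 26868 passed, of which 698 rose and 1051 fell. Of 86 cilia structure genes 64 fell and 0 rose (84 and 0 adjusted over the list alone). They included ift88.S (-1.51 ± 0.19, adjusted p = 0.0187), the adenylate kinase gene ak7.S (-2.16 ± 0.29, adjusted p = 0.0214) and spag6.S (-1.68 ± 0.24, adjusted p = 0.0232). The median level of the cilia genes with this morpholino was 4.71, 4.85 and 2.75 log2 CPM in replicates 1, 2 and 3, so that replicate 3 again lay lowest. Of 36 multiciliated cell regulators 13 fell (18 adjusted over the list alone). Among them were mcidas.S (-1.61 ± 0.31, adjusted p = 0.0309), tp73.L (-1.60 ± 0.32, adjusted p = 0.0331) and the centriolar gene cep164.S (-1.65 ± 0.34, adjusted p = 0.0349). In the goblet and mucus list 3 of 31 fell (4 adjusted over the list alone). These were itln1.L by 2.64 ± 0.56 (adjusted p = 0.0356), the mucin glycosyltransferase gene galnt4.L by 1.51 ± 0.35 (adjusted p = 0.0412) and foxq1.L. Of 16 small secretory cell genes 3 fell (6 adjusted over the list alone), with slc18a1.S falling by 2.14 ± 0.50, rab3a.S by 1.56 ± 0.33 and the vesicle GTPase rab27a.S by 1.41 ± 0.30. No ionocyte or basal cell gene passed (0 adjusted over either list alone). With the block 2 ionocyte genes fell, the proton pump subunit atp6v0d1.L (-0.74, adjusted p = 0.0473) and slc26a4.L (-2.17, adjusted p = 0.0444), and no basal cell gene did. Without it, atp6v0a1.L was at -1.69 ± 0.44 (adjusted p = 0.0542) and cdh3.L at 0.97 ± 0.28 (adjusted p = 0.0704).

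Among the genes that rose with the foxq1 morpholino at the early time, the p53 and morpholino response list held 5 of 60 (7 adjusted over the list alone), and with the block 1 other member fell. They included the repair gene xpc.L (1.80 ± 0.26, adjusted p = 0.0232), eda2r.L (1.99 ± 0.33, adjusted p = 0.0273) and aen.L (0.97 ± 0.22). The cell cycle list held 12 of 108 (16 up and 1 down adjusted over the list alone), with the cyclins ccnb1.S at 3.23 ± 0.52, ccna2.S at 1.17 ± 0.19 and ccne1.S at 1.45 ± 0.26. Of 24 hes and hey genes 3 rose (6 up and 1 down adjusted over the list alone). These were hes5.5.L (2.00 ± 0.38, adjusted p = 0.0298), hes6.1.S (1.3 ± 0.29, adjusted p = 0.0384) and hes5.2.L, which had at most 1.76 CPM in any library. The Notch pathway list, which shares hes5 members with it, had 4 risers of 75 (6 adjusted over the list alone, and 1 faller with the block), including dll1.L (1.83 ± 0.26, adjusted p = 0.0232) and the ligand-activating ubiquitin ligase mib1.S (0.82 ± 0.19). Both xbp1 homeologs rose, xbp1.L by 0.90 ± 0.17 and xbp1.S by 0.67 ± 0.16, as 2 of 98 endoplasmic reticulum genes (1 adjusted over the list alone). In turn 2 of 78 superficial epithelium genes fell (1 adjusted over the list alone, 6 over all genes with the block), dsp.L by 1.07 ± 0.20 and cldn4.S by 1.00 ± 0.25. The largest single rises were lonrf3.S (7.32 ± 0.67), hebp2.L (7.20 ± 0.56), lonrf3.L (6.38 ± 0.68), the LIM homeobox gene lhx5.L (4.21 ± 0.91), nif.L, the photolyase gene xl64phr (3.86 ± 0.45), lonrf1.L and lonrf1.S. The largest falls were dnah2.L (-3.91 ± 0.86), dzip1l.S, tacr1.S, tex33.L, the axonemal gene spag17.L, dzip1l.L, odf3.S and odf3.L (-3.35 ± 0.83). Of these, tacr1.S, spag17.L and odf3.L did not pass with the replicate block (adjusted p = 0.0522, 0.0538 and 0.0528). Of the other tissues, 1 of 26 neural crest genes fell (0 adjusted over the list alone, 2 over all genes with the block). Further, 1 heat shock and stress gene of 47 rose and 1 fell (1 and 1 adjusted over the list alone, 1 and 2 over all genes with the block), and 1 mesoderm and muscle gene of 36 rose and 1 fell (0 adjusted over the list alone, 1 and 0 over all genes with the block). None passed among neural, endoderm, blood and immune, or cement gland and hatching gland genes (0 adjusted over each list alone). With the block 3 cement gland and hatching gland genes, 1 member of the endoderm list and 1 blood and immune gene fell, and no neural gene passed. The endoderm list member was endod1.L (-1.01, adjusted p = 0.0478 in the blocked edgeR test). It had 235 CPM in uninjected explants, so its fall need not speak of endoderm.

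By camera, the foxq1 morpholino lists lower at the early time were cilia structure (adjusted p = 1.17e-46), multiciliated cell regulators (1.15e-07), superficial epithelium (0.000334), small secretory cell (0.00086), goblet and mucus (0.000938) and ionocyte (0.0035). With an estimated correlation none of these passed (adjusted p = 0.681, 0.718, 0.718, 0.681, 0.681 and 0.736). Those higher were cell cycle (adjusted p = 9.87e-05), hes and hey (0.000204) and p53 and morpholino response (0.00262), each with adjusted p = 0.718 with an estimated correlation. The ionocyte call also ended without replicate 1 (adjusted p = 0.413). This comparison rested on few libraries: the count of 1749 genes became 0 without the stage term, 4739 by DESeq2, 0, 805 and 5 without replicate 1, 2 or 3, and 18 with only the 2 groups in the fit. Leaving out uninjected replicate 1 or 3 gave 16 or 42 genes, and leaving out foxq1 morpholino replicate 1 or 3 gave 27 or 17.

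The gene lists were also compared pair by pair, each morpholino library against the uninjected library of the same replicate number. The median log2 difference of the cilia genes at the early time was -1.51, -1.15 and -2.97 in the 3 pairs of the spdef morpholino and -1.75, -0.92 and -2.44 in those of the foxq1 morpholino. For the p53 and morpholino response genes it was 0.78, 0.45 and 1.11 with the spdef morpholino and 0.52, 0.1 and 0.46 with the foxq1 morpholino.

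**Figure D2:**
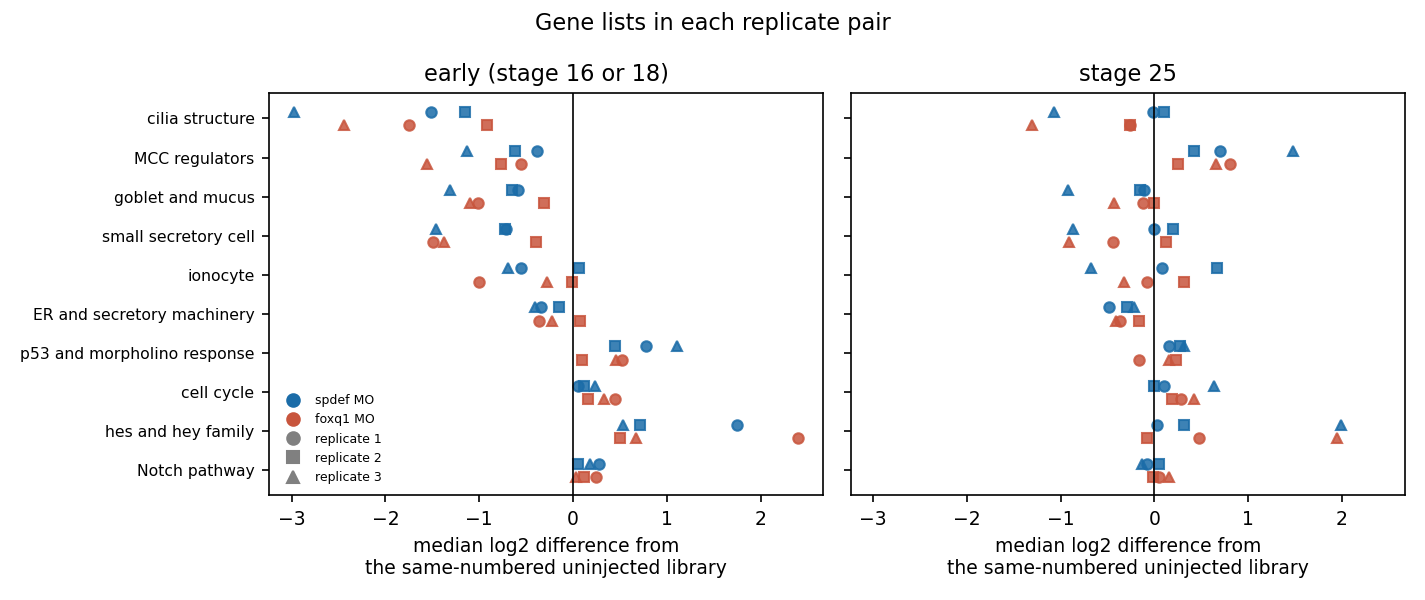
Median log2 difference (horizontal axis) of 10 gene lists between each morpholino library and the uninjected library of the same replicate number, at the early time (left) and at stage 25 (right); colours mark the morpholino and symbols the replicate. Cilia genes lay below 0 in all early pairs, from -2.97 to -0.92, and multiciliated cell regulators lay below 0 in all early pairs and above 0 in all stage 25 pairs.

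The morpholinos were then compared with each other. At the early time 96 genes differed, 61 higher and 35 lower with the spdef than with the foxq1 morpholino. Higher with the spdef morpholino were, by the largest differences, rnf24.L (log2 fold change 3.18 ± 0.31, adjusted p = 0.0187), ccdc141.S (3.12 ± 0.51), ccdc134.S (2.99 ± 0.43) and the phosphoinositide 3-kinase regulator pik3r6.S (2.92 ± 0.44). Higher with the foxq1 morpholino were rassf7.L (-2.46 ± 0.19, adjusted p = 0.00677), rab3ip.L (-1.83 ± 0.26), ugp2.L (-1.80 ± 0.25), spata2l.L and scaf4.L (-1.65 ± 0.18). The count was 0 without the stage term, 0 on leaving out replicate 1, 2 or 3, and 1209 by DESeq2. It was 371 without a filter on low counts, 44 with homeologs summed and 50 with only the 2 groups in the fit. Leaving out one spdef morpholino library left 5, 3 or 42 genes (replicates 1, 2 and 3) and leaving out one foxq1 morpholino library left 0, 1 or 1.

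Genes past the threshold in both early comparisons in the same direction numbered 418 up and 818 down, and 0 went in opposite directions. Independent lists of these sizes would share 39.3 and 75.4. Both comparisons use the same 3 uninjected libraries, and groups simulated without any change against these controls shared at most 0 genes. Across genes, which are not independent replicates, the log2 fold changes had a covariance of 0.832 (0.149 simulated) and a correlation of 0.78 (0.51 simulated). The 3 controls cannot be split into separate sets of at least 2 libraries, so part or all of the excess over the independent lists may come from the shared controls. The shared count was 0 without the stage term and 0, 519 and 5 without replicate 1, 2 or 3.

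At stage 25, 12 genes rose and 5 fell with the spdef morpholino among 26879 tested. With the replicate block 466 rose and 399 fell, including all 17. The genes that rose were led by the methionine sulfoxide reductases msrb1.L (3.69 ± 0.46) and msra.1.L (2.64 ± 0.32), wdr76.S (2.99 ± 0.33), fam213b.L (2.76 ± 0.32), the glutaredoxin gene glrx.L (2.65 ± 0.33), adck1.L (2.62 ± 0.27), the photolyase gene xl64phr (2.49 ± 0.31) and the chromatin remodeller gene chd9.L (2.08 ± 0.26). Lower were the spermine synthase gene sms.L (-3.57 ± 0.43), with 74.5, 43.1 and 38.1 CPM in the uninjected libraries and 5.81, 4.07 and 2.74 CPM with the morpholino. Also lower were the apoptosis effector gene bak1.L (-2.27 ± 0.27), the cysteinyl-tRNA synthetase gene cars.S (-1.71 ± 0.21) and the peroxisomal import receptor gene pex5.S (-1.64 ± 0.21), all with adjusted p = 0.0475. No member of any of the 19 lists passed over all genes tested. Adjusted over the list alone, 5 p53 and morpholino response genes rose and 1 fell, 1 basal cell gene rose and 1 endoplasmic reticulum gene fell. With the replicate block 10 p53 and morpholino response genes rose of 66, such as plk2.S (1.99, adjusted p = 0.0178) and xpc.L (1.86, adjusted p = 0.0261). The block also gave 6 endoplasmic reticulum genes lower, such as the coat gene copz1.L (-1.27, adjusted p = 0.0238), 4 goblet and mucus genes lower, such as ern2.S (-1.06, adjusted p = 0.0449), and 5 cell cycle genes higher and 1 lower. It further gave 4 multiciliated cell regulators higher, such as e2f4.L (1.42, adjusted p = 0.0496), and 3 ionocyte genes higher and 1 lower, such as foxi1.L (1.56, adjusted p = 0.0299). With the block 3 mesoderm and muscle genes fell and 2 blood and immune genes rose, including gata2.L (1.78, adjusted p = 0.0217). It gave 1 gene lower in each of the cilia structure, superficial epithelium and endoderm lists, 1 higher in each of the Notch pathway, neural and neural crest lists, and 1 higher and 1 lower in the basal cell list. In the multiciliated cell group, the replicate 3 library stood apart, as in its 509 CPM of mcidas.S against 7.29 and 4.71 CPM in replicates 1 and 2.

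By camera at stage 25, the lists lower with the spdef morpholino were endoplasmic reticulum (adjusted p = 0.000452), cilia structure (0.0115), mesoderm and muscle (0.0211) and goblet and mucus (0.0293). Those higher were multiciliated cell regulators (0.00216), p53 and morpholino response (0.00291) and cell cycle (0.00607), with adjusted p values of 0.681 to 0.845 with an estimated correlation. Without replicate 3 the cilia list turned upward (adjusted p = 0.413) and the goblet and mucus and cell cycle calls ended (0.148 and 0.25). The mesoderm and muscle call ended without replicate 1 or 2 (0.0558 and 0.107). The count of 17 genes became 0 on leaving out each of the 6 libraries in turn, 0, 0 and 79 without replicate 1, 2 or 3, and 843 by DESeq2. With the replicate block on replicates 1 and 2 alone, an alternative chosen after the data were seen, it was 4267.

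The foxq1 morpholino at stage 25 raised 10 genes and lowered 0 (DESeq2, 451 in both directions; 2082 genes at an unadjusted p under 0.05). With the replicate block 65 rose and 40 fell, the 10 among them. The angiotensin receptor gene agtr2.L rose by 6.80 ± 0.59 (adjusted p = 0.0365), with 48.3, 35.1 and 19.2 CPM against at most 0.419 CPM in the uninjected libraries. The others named by the rule were msra.1.L (3.12 ± 0.33), fam213b.L (2.95 ± 0.32), xl64phr (2.86 ± 0.31), wdr76.S (2.80 ± 0.33), rassf7.L (2.51 ± 0.26) and adck1.L (2.42 ± 0.27). Of these, rassf7.L had 445 to 580 CPM with the foxq1 morpholino and 73.9 to 114 CPM in the other stage 25 libraries. No list member passed over all genes tested, while adjusted over the list alone 2 p53 and morpholino response genes and 1 blood and immune gene rose, and 1 superficial epithelium gene rose and 1 fell. With the block the 2 p53 response genes were eda2r.L (2.43, adjusted p = 0.0414) and xpc.L (1.95, adjusted p = 0.0483). The block also gave 1 ionocyte gene higher, and 1 goblet and mucus gene and 1 heat shock and stress gene lower. The cilia gene tekt3.L had a log2 fold change of -1.81 ± 0.48 (adjusted p = 0.439).

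By camera, the lists lower with the foxq1 morpholino at stage 25 were cilia structure (adjusted p = 2.25e-08) and endoplasmic reticulum (0.000134). Those higher were cell cycle (0.000104), multiciliated cell regulators (0.0191), endoderm (0.0215) and hes and hey (0.0297), with adjusted p values of 0.718 to 0.78 with an estimated correlation. The blood and immune list passed with the replicate block alone (adjusted p = 0.0547 without and 0.00352 with it). The replicate 3 library stood apart in the multiciliated cell group, with a list median of 5.43 log2 CPM against 3.66 and 2.82 in replicates 1 and 2. Without replicate 3 the hes and hey list turned downward (adjusted p = 0.912) and the cilia and endoderm calls ended (0.106 and 0.336). The count of 10 genes was 0 on leaving out replicate 1, 2 or 3, 0 on leaving out uninjected replicate 1, 2 or 3 or foxq1 morpholino replicate 1, and 1 on leaving out foxq1 morpholino replicate 3. The added block on replicates 1 and 2 gave 2236.

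Between the morpholinos at stage 25, edgeR called 0 genes (1802 at an unadjusted p under 0.05; DESeq2, 480), and the replicate block called 25 higher and 24 lower with the spdef morpholino. Genes past the threshold in both stage 25 comparisons in the same direction numbered 6, or 70 with the block, with a covariance of the log2 fold changes of 0.714 (0.267 simulated for unchanged groups). Whether a morpholino's effect at stage 25 differed from its early effect was tested by an interaction term over all 18 libraries. It called 0 genes for the spdef morpholino (2797 at an unadjusted p under 0.05; DESeq2, 268) and 0 for the foxq1 morpholino (2457; DESeq2, 168), and the fits with the replicate block called 0 for both. The larger early counts are therefore not shown to differ from those at stage 25. They also come from unlike fits, since the stage term, which sets replicate 3 apart, is in the early fits only. Without that term the early counts were 0 (spdef) and 0 (foxq1). With the block at both times they were 4374 and 2289 early against 865 and 105 at stage 25. The block on replicates 1 and 2 alone, added after the data were seen, reversed this order. It gave 1352 and 9 early against 4267 and 2236 at stage 25, so which time has more calls depends on replicate 3.

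**Figure D3:**
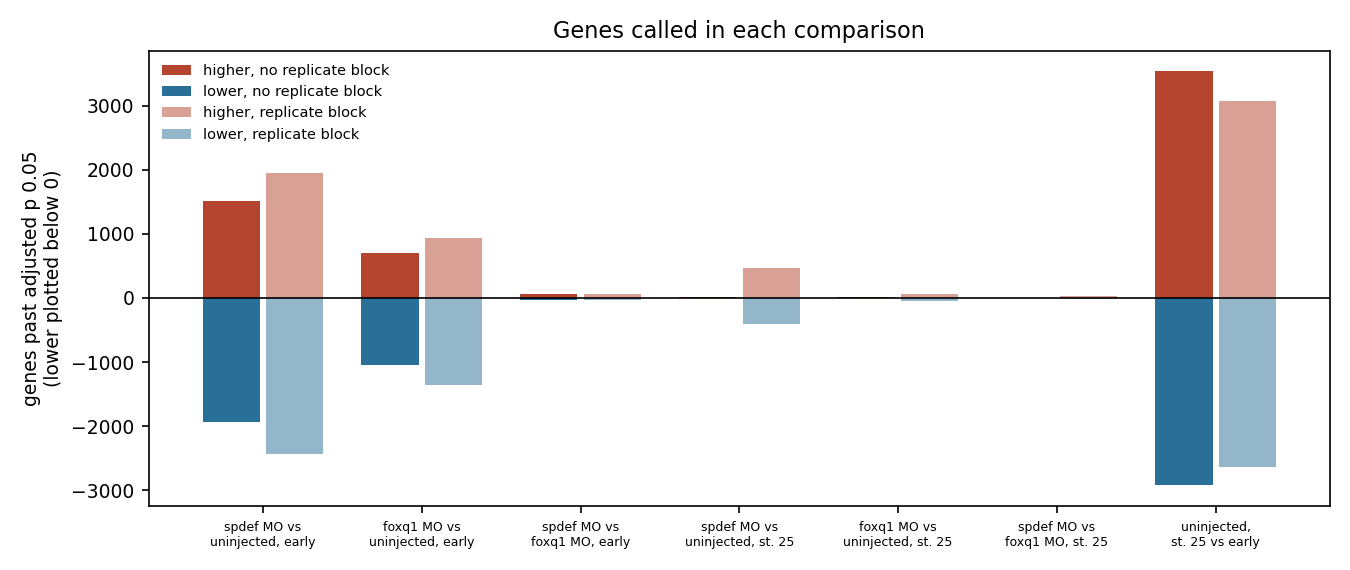
Number of genes past an adjusted p of 0.05 (vertical axis, linear; lower genes plotted below 0) in 7 comparisons, without (solid bars) and with (pale bars) the replicate block. With the spdef morpholino 1514 genes rose and 1928 fell at the early time, and 12 rose and 5 fell at stage 25, or 466 and 399 with the block. The solid bars of the early time are from fits with the stage term, which sets replicate 3 apart, and those of stage 25 are not.

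Uninjected explants changed between the early time and stage 25 in 6453 of 25521 genes, of which 3531 rose and 2922 fell. Regulators of multiciliated cell formation fell in 18 of 37 cases and 0 rose (20 and 0 adjusted over the list alone). Among them mcidas.S fell by 8.08 ± 0.86 (adjusted p = 0.00642), from 335 ± 69.2 to 1.23 ± 1.19 CPM, with mcidas.L, the cyclin O genes ccno.S (-7.43 ± 0.65) and ccno.L (-7.21 ± 0.87), foxn4.L (-3.95 ± 0.37) and cep152.L (-3.86 ± 0.32). Of 85 cilia structure genes 3 rose and 0 fell (2 and 0 adjusted over the list alone; with the block 2 rose and 1 fell), led by the tektin genes tekt3.S (3.75 ± 0.66) and tekt3.L (3.34 ± 0.60). Ionocyte genes rose in 24 of 58 cases and fell in 1 (28 and 2 adjusted over the list alone, 26 and 2 over all genes with the block), including the proton pump subunits atp6v1h.L (1.98 ± 0.24) and atp6v0a1.S (2.38 ± 0.31). Goblet and mucus genes rose in 10 of 33 cases and fell in 4 (14 and 5 adjusted over the list alone), with the mucin glycosyltransferase genes galnt3.S and galnt3.L at 1.92 ± 0.24 and 3.38 ± 0.49. The mucin gene muc1.S rose from at most 0.0413 CPM to between 5.14 and 6.65 CPM. Of the targeted genes spdef.S fell by 3.69 ± 0.63 (adjusted p = 0.0124), foxq1.S rose by 2.34 ± 0.45 (adjusted p = 0.0152) and foxq1.L had -1.04 ± 0.69 (adjusted p = 0.293). With homeologs summed, foxq1 had a log2 fold change of -0.3.

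Cell cycle genes fell with stage in 64 of 108 cases and rose in 1 (85 and 2 adjusted over the list alone), including ccne2.L (-3.39 ± 0.39), mcm2.L (-2.59 ± 0.30) and e2f3.L (-1.83 ± 0.22). Of 19 hes and hey genes 9 fell (11 adjusted over the list alone), such as hes9.1.S (-5.06 ± 0.62), hes5.1.L and hes5.5.L (-4.82 ± 0.83). Of 71 Notch pathway genes 22 fell and 11 rose (23 and 13 adjusted over the list alone, 17 and 7 over all genes with the block). Among them were dlc.L at -6.39 ± 0.86 and the ligase gene mib2.L at 2.52 ± 0.33. Neural genes fell in 11 of 34 cases and rose in 2 (15 and 2 adjusted over the list alone, 13 and 1 over all genes with the block), including irx1.S (-3.52 ± 0.47) and sox3.L (-3.94 ± 0.66). Endoplasmic reticulum genes rose in 14 of 98 cases and fell in 4 (12 and 3 adjusted over the list alone), with the chaperone gene hspa5.S at 1.87 ± 0.22. Superficial epithelium genes rose in 6 and fell in 13 of 78 cases (6 and 12 adjusted over the list alone), with krt18.L at -3.22 ± 0.39. Of the remaining lists, risers and fallers over all genes tested numbered 7 and 1 of 37 for basal cell (7 and 1 adjusted over the list alone), 2 and 2 of 16 for small secretory cell (2 and 2), and 13 and 4 of 63 for p53 and morpholino response (13 and 5). They numbered 9 and 3 of 45 for heat shock and stress (10 and 3), 3 and 3 of 25 for neural crest (3 and 3), and 7 and 7 of 35 for mesoderm and muscle (10 and 8). They numbered 0 and 2 of 9 for endoderm (0 and 2), 2 and 4 of 17 for blood and immune (2 and 5), and 2 and 4 of 14 for cement gland and hatching gland (3 and 5). With the block they numbered 1 and 2 for small secretory cell, 5 and 4 for neural crest, 1 and 5 for blood and immune, and 2 and 1 for cement gland and hatching gland.

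The genes with the largest rises with stage in uninjected explants included the proteoglycan gene ogn.L (8.94 ± 1.11, from at most 0.413 CPM to 277, 139 and 28.4 CPM) and lum.L and lum.S. Others were ahnak2.S (9.40 ± 1.18), g6pc-like.1.L (9.39 ± 1.82), egfl6.S, fgfbp2.L and g6pc1.3.S. The last 3 and lum.S had at most 0.124 CPM in each early uninjected library, so that their fitted fold changes depend on the prior count. The lowest of the 3 stage 25 values was that of replicate 3 for each of these genes, such as 0.792 CPM of egfl6.S against 64.5 and 20.5 CPM. The largest falls, besides mcidas and ccno, were those of the Wnt ligand gene wnt11b.L (-7.37 ± 0.89), the pluripotency factor gene pou5f3.2.L (-7.29 ± 1.60), onecut1.2.S (-7.16 ± 0.99) and foxi4.2.L (-7.09 ± 1.34). By camera, lists lower at stage 25 were cell cycle (adjusted p = 2.31e-21), multiciliated cell regulators (1.1e-11), hes and hey (2.39e-05), neural (0.000294) and Notch pathway (0.0496). Those higher were ionocyte (1.77e-06) and goblet and mucus (0.0496; 0.0684 with the replicate block), with adjusted p values of 0.681 to 0.718 with an estimated correlation. Without replicate 3 the goblet and mucus and Notch pathway calls ended (adjusted p = 0.0802 and 0.124). The count of 6453 genes was 0, 0 and 9474 without replicate 1, 2 or 3, and 9869 by DESeq2. It was 1806, 1021 and 1302 without early replicate 2, stage 25 replicate 1 or stage 25 replicate 2.

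Developmental position was read from 35 genes of the blastula and gastrula measured here and from an index built on the uninjected libraries, in which early controls lie near 0 and stage 25 controls near 1. The median over the 35 genes of the log2 difference between a morpholino library and the uninjected library of the same replicate number was above 0 in 12 of 12 pairs, with a mean of 1.18. The index was lower in 10 of 12 pairs, with a mean difference of -0.17 over all pairs. The exceptions were the early replicate 3 pairs of the spdef and foxq1 morpholinos, at 0.191 and 0.141, in which the multiciliated cell regulators had their lowest early median differences (-1.13 and -1.56) and the cilia genes theirs (-2.97 and -2.44). At stage 25 it was 1.096, 1.089 and 0.625 in uninjected replicates 1, 2 and 3, 0.971, 0.908 and 0.113 with the spdef morpholino, and 0.851, 0.971 and 0.201 with the foxq1 morpholino.

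**Figure D4:**
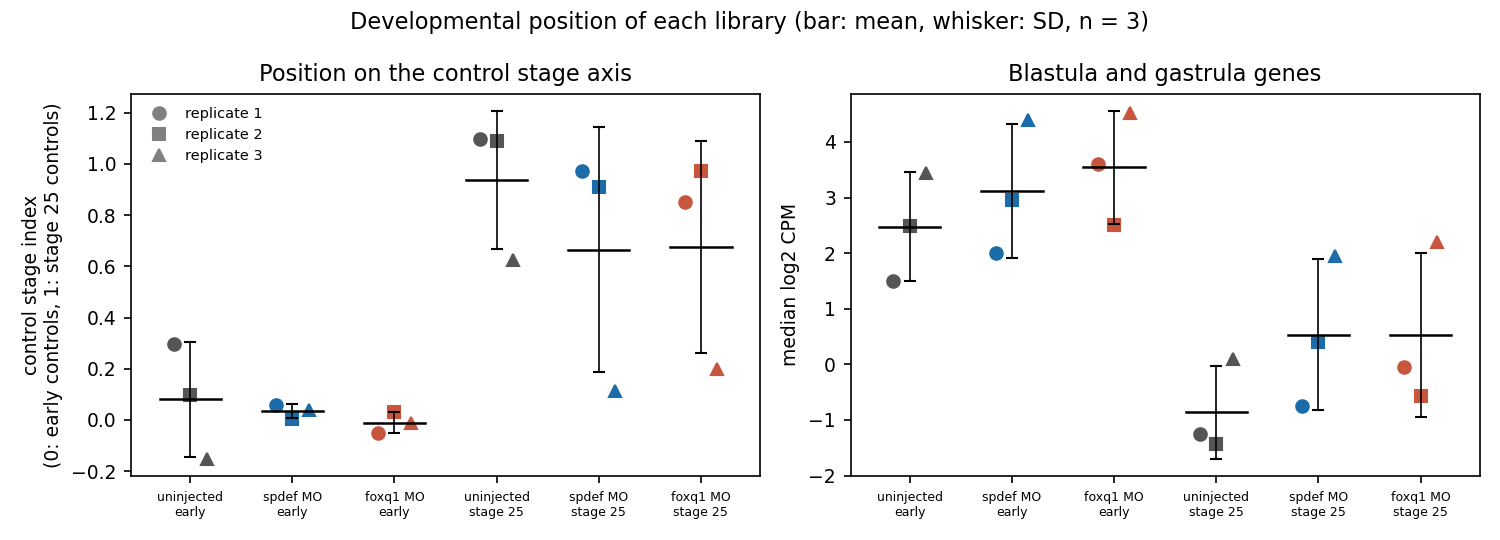
Control stage index (left, vertical axis without unit) and median log2 CPM of 35 blastula and gastrula genes (right) in each of the 18 libraries, grouped by treatment and time; symbols mark the replicate number, bars the group mean and whiskers the SD over 3 libraries. At stage 25 replicate 3 had the lowest index of each treatment, from 0.113 to 0.625.

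The authors' deposited tables give their own DESeq2 comparisons of each morpholino with uninjected explants. At the early time the authors' deposited table for the spdef morpholino has 3817 genes past an adjusted p of 0.05, 1471 higher and 2346 lower. That for the foxq1 morpholino has 1607, 476 higher and 1131 lower. At stage 25 the deposited table for spdef has 2608, 1090 higher and 1518 lower, and the deposited table for foxq1 lists 1357 genes, all past 0.05, with 498 higher and 859 lower. Of the authors' calls that were tested here, 100%, 100%, 98.9% and 99.5% had the same direction as in the fits reported above, in that order. The genes called in both numbered 2508, 1096, 17 and 10, and 2738, 1137, 751 and 102 with the replicate block. Of the called genes named above for the early time, some did not pass in the deposited DESeq2 tables. With the spdef morpholino they included endod1.S (adjusted p = 0.284) and sec24d.S (0.0522). With the foxq1 morpholino they included cldn4.S (adjusted p = 0.286), spag17.L (0.269), xbp1.S (0.194), aen.L (0.134), mib1.S (0.115), galnt4.L (0.11), rab3a.S (0.0842), xbp1.L (0.0786) and rab27a.S (0.0562). The deposited tables were made from these same libraries, so that they are not independent of the values above.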

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

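The interaction test of this list, the means without replicate 3, the tests that use the index and the test of blastula and gastrula genes were chosen after the result was seen, the last after the morpholino libraries had been seen to shift on the first principal component in 12 of 12 pairs. The multiciliated cell regulators went in opposite directions at the early time and at stage 25: the mean log2 difference over pairs was -0.71 and 0.87 with the spdef morpholino, a difference of 1.58, and -0.96 and 0.57 with the foxq1 morpholino, a difference of 1.53. Replicate 3, which stood apart, added to this: without it the means were -0.5 and 0.56 with the spdef morpholino, a difference of 1.06, and -0.66 and 0.53 with the foxq1 morpholino, a difference of 1.19. The camera test of the interaction gave adjusted p = 6.58e-09 and 1.13e-09 with a preset correlation, and adjusted p = 0.435 for both with an estimated correlation; it was not particular to this list, since 7 and 9 of 19 lists passed it with the preset correlation and 0 with an estimated one, cilia structure with adjusted p = 8.79e-24 and 1.11e-15. In uninjected explants 18 of 37 genes of this list fell with stage and 0 rose.

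A candidate explanation is slower development after injection, which may leave early regulators low at first and high later. The median log2 difference of the 35 blastula and gastrula genes was above 0 in 12 of 12 pairs, with a mean of 1.18, and the index differed by a mean of -0.17, but over the 3 experiments each exact sign-flip test gave p = 0.25, the smallest that 3 can give, so this stays open. The first of these tests largely restates the shift on the first component. Overlaps of the early calls with the genes that change with stage decide nothing, since both use the same early uninjected libraries. With the index in the fit 90.3% of the early spdef calls and 56.5% of the early foxq1 calls stayed past the threshold, but the fold changes of these calls moved by a median of 0.05 and 0.1 (median SE 0.33 and 0.32), so whether a shift along this axis is the whole cause stays open as well.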

How the results depend on the processing

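The index covariate and the replicate block on replicates 1 and 2 were chosen after the data were seen; all other settings were fixed before. The cause of the changes below was not tested, except that leaving out libraries leaves fewer degrees of freedom. DESeq2 gave 6171 and 4739 genes for the spdef and foxq1 morpholinos at the early time, 843 and 451 at stage 25, 1209 and 480 between morpholinos at the early time and stage 25, 9869 for the control stage comparison, 268 and 168 for the interactions, and 3095 and 136 shared genes at the early time and stage 25. Without the stage term the early counts were 0 (spdef), 0 (foxq1), 0 (between morpholinos), 0 (shared) and 0 targeted genes; DESeq2 was not run without it. With only the 2 groups in the fit the counts were 1995, 18 and 50 early and 0 and 0 at stage 25. The replicate block gave 865 and 105 genes at stage 25, 49 between morpholinos and 70 shared. It changed no other count of called or shared genes over a whole comparison by over 1.5 times, but moved counts within some lists by more, as given above. On replicates 1 and 2 alone it gave 1352, 9 and 7 early, 8 shared, 4267, 2236 and 1925 at stage 25, 1099 shared, and 12363 for the control stage comparison. With the index as a covariate the counts were 153, 42 and 128 at stage 25, 22 shared there, and 22 between morpholinos early. Without a filter 371 genes differed between morpholinos early and 10 were shared at stage 25. With homeologs summed the counts between morpholinos were 44 and 1, and foxq1 had -0.3 with stage in place of a rise.

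Leaving out a replicate number or a single library gave 54 to 2745 genes (spdef early), 0 to 1862 (foxq1 early), 0 to 42 (between morpholinos early), 0 to 79 (spdef stage 25), 0 to 9 (foxq1 stage 25) and 0 to 9474 (control stage). Between morpholinos at stage 25 every such count was 0. Leaving out a replicate number gave 0 for the interactions, for which no single library was left out, 0 to 519 shared genes early, 0 at stage 25, and 0 to 1 targeted genes. Of the 95 list tests 39 passed, 0 with an estimated correlation, 1 by fry, 0 by fry with the block, 38 by camera with the block and 34 to 44 without a replicate. By camera with the preset correlation, the cilia list with the spdef morpholino at stage 25 had adjusted p from 1.48e-06 to 0.413. It had adjusted p = 0.845 by camera with an estimated correlation and 0.719 by fry. The hes and hey list with the foxq1 morpholino at stage 25 ran from 0.000101 to 0.912 with the preset correlation. Each of these 2 lists turned in direction without replicate 3. Of 327 results of named genes, 321 kept their call and direction with RLE factors, 281 with DESeq2 (45 more passed), and 300 with the replicate block (16 more passed, 9 no longer passed). Without replicate 1, 2 or 3, 210, 155 and 123 of them no longer passed, and 114, 169 and 193 kept their call and direction.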

Other observations

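The tests of shared controls, injection, a common pathway, a younger replicate 3, depth and exchanged libraries were chosen after the results were seen, and so were the genes named here. Several genes differed in a tight pattern across both times. The gene rassf7.L had 539, 404 and 351 CPM with the foxq1 morpholino at the early time and 580, 445 and 500 CPM at stage 25, against 52.4 to 129 CPM in the other 12 libraries. The spdef morpholino libraries had low cars.S, a cysteinyl-tRNA synthetase gene, at 20.8, 25.7 and 21.3 CPM early and 20.8, 18.9 and 17 CPM at stage 25, where the uninjected libraries had 53.8 to 74.5 CPM. At the early time cars.S fell by 1.37 ± 0.17 with the spdef morpholino (adjusted p = 0.00508 by edgeR).

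A further set of genes was high with both morpholinos at both times. The gene fam213b.L rose by 3.07 ± 0.22 and 3.19 ± 0.22 on the log2 scale at the early time with the spdef and foxq1 morpholinos (adjusted p = 0.000982 and 0.001 by edgeR). The photolyase gene xl64phr had 20.8 to 37.8 CPM in the early morpholino libraries and 18.2 to 32.2 CPM in those of stage 25, against at most 4.73 CPM in the 6 uninjected libraries. The gene wdr76.S had 51.6 CPM or more in each of the 12 morpholino libraries and at most 23.9 CPM in the uninjected ones.

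At the early time 1236 genes passed in one direction with both morpholinos, of 3442 and 1749 called with each, a number that was 0, 519 and 5 without replicate 1, 2 or 3. The covariance of the log2 fold changes was 5.27 times the highest of the simulated unchanged groups. The simulation drew each gene separately, while genes here moved together (estimated correlation 0.62 and 0.64 in the cilia list with the spdef and foxq1 morpholinos). It therefore cannot decide whether the shared controls are the whole source. A response to injection of any sequence may explain the shared genes, and so may a common pathway of spdef and foxq1. The design holds 0 libraries with a control morpholino, and 2 foxq1 homeologs fell with the spdef morpholino, which either explanation allows, so these cannot be told apart.

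Libraries of replicate 3 stood apart from the others. Sequencing depth is argued against, since 5 of 6 of these libraries had totals within the range of the other 12. The highest index of an early library was 0.296. For uninjected replicate 3 the index argues against an exchange of early and stage 25 libraries, at -0.151 early and 0.625 at stage 25. It cannot decide this for the morpholino libraries of replicate 3, which were low at both times. They had 0.04 and 0.113 (spdef) and -0.01 and 0.201 (foxq1). Replicate 3 may be younger than its stage label: the blastula and gastrula genes of its early control lay 0.97 above the higher of the other early controls on the log2 scale. Their median was highest in replicate 3 of every group, at 3.45, 4.39 and 4.53 log2 CPM early (uninjected, spdef, foxq1) and 0.1, 1.95 and 2.21 at stage 25. Its early control had the lowest index of the early controls (-0.151, against 0.296 and 0.098), while its early morpholino libraries were not lowest in their groups (0.04 and -0.01). The other early controls differ by 0.98 between themselves and all these libraries are of 1 experiment, so the age of replicate 3 stays open. Besides age no biological explanation was tested.

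Other splits of the libraries were run for each count of genes. In the comparisons of 3 against 3 with calls, only 1 of 10 splits, the real one, gave any: 3442 and 1749 genes for the spdef and foxq1 morpholinos early, 17 and 10 at stage 25, 96 between morpholinos early and 6453 for the control stage comparison, with 0 as the highest other in each. The 10 splits cannot give a share under 0.05. Between morpholinos at stage 25 the real count was 0, as for each interaction, so that 10 of 10 and 15 of 15 splits tied and nothing was tested. With the replicate block the real split gave 865 and 105 genes for the spdef and foxq1 morpholinos at stage 25 and 49 between them, with 0 as the highest other in each. Every other split mixes the 2 groups compared, so few calls are expected there. Only 4 of the 10 splits, the real one included, part all 3 same-numbered pairs. The splits therefore add no support, with or without the block.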
